A study of Rattus norvegicus with 9 samples.

How the data were processed

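Liver RNA of 9 female Wistar pups was compared, 4 controls and 5 pups separated from their mothers for 4 h and returned for 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was checked by capillary electrophoresis, and 200 ng per pup was labelled with Cy3 by a low-input, single-colour kit that amplifies RNA from its 3′ end. Per the file headers, 1 sample was hybridised per array of a rat design with 4 arrays on a slide, whose probe coordinates are of the rn4 build.

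Each array's scanner file holds 44254 spots. Per the file headers, its processed signal is a linear intensity from which the scanner software had subtracted a spatially fitted background and which it had not normalized between arrays, and its mean signal and local background are intensities without correction. The submitters' processing notes name Agilent Feature Extraction 10.10 and limma, the latter without a version. The deposited value table of the series gives log2 values of 17604 probes. All of these were found on the array and its columns correlated with the same arrays' log2 scanner signals at 0.992 to 0.995. The log2 scale was settled by that comparison, and no gene-wise centring was evident. Its column medians were 9.42, 9.46, 9.42 and 9.47 for controls 1 to 4 and 9.41, 9.51, 9.48, 9.47 and 9.52 for separated pups 1 to 5, and its highest value was 19.0 on every array. The normalization and the choice of probes behind it are not given in the sources used here, and the table served as an alternative.

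Control spots and spots that the scanner software called outliers were left out, saturated spots were kept, and spots of the same probe were averaged, which left 30367 probes from 42877 spots. The values tested were log2 processed signals minus the array's 75th percentile. A probe was kept when it was well above background on at least 4 of the 9 arrays regardless of group, which left 18814 probes. Genes were named through the accession of the probe for 18006 probes, through the file's symbol for 2654 and through a synonym for 559, with a gene table of the GRCr8 assembly used for names alone. The other 9148 probes kept the file's name and are not counted as genes, and 288 changed probes were among them. The brightest probe over all 9 arrays stood for a gene. A probe not well above background on any array of a group has only a bound there. It is given as "at least" a fold, the brighter group's mean against the mean, per array of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background.

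Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. There were 30 functional lists and 19 cell type lists. They were tested with camera at a preset correlation of 0.01 when at least 5 members were measured, with adjustment over the lists of a kind. Camera with an estimated correlation and fry were run beside it. The mean level of a list per pup was compared by an exact two-sided permutation test over the 126 splits of 9 pups into 4 and 5, whose smallest p is 0.0159. The groups, the lists and their tests, the gene test, the rule for naming genes and the alternatives were fixed before the data were examined, apart from the tests and alternatives that the text says were chosen after. The rule named the 12 genes with the largest log2 difference in each direction among those past the threshold, every list member past it, up to 4 members of smallest p in lists that are described, and genes tied to the question, of which those reported are Lbp, Cd14, Tlr4, Hamp, Lcn2, A2m, Fkbp5, Tsc22d3, Pck1 and Cyp7a1. Mcm4, Pcna, Hbb, Hbb-b1, Fabp4, Retn, Cidec and Cfd fall outside it and were chosen after their values were seen, as was the count of genes whose groups do not overlap. Some genes that the rule names are not reported here.

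Slide did not enter the main model and was a block in alternatives. Slide 1 held 2 controls and 2 separated pups, slide 2 held 2 controls and 1 separated pup, and slide 3 held 2 separated pups. The alternatives changed the scaling, the background correction (normexp with an offset of 50, or none), the values, the filter, the slide or replicate number as a block, the variance model, array weights, the probe that stands for a gene, and the pups included. The 5′ and 3′ ends were compared in genes with at least 2 tested probes on 1 strand, 60 to 500000 bp apart in the rn4 coordinates of the files. On simulated arrays with the measured means and spreads, where 200 of 18719 probes had been changed (11919 genes), the separation comparison called 60.0% of the probes changed by a fold of 2 and 94.0% of those changed by a fold of 4, and 4.35% of its calls outside the shifted list were false. The list test called a list of 30 genes that had been shifted and 0 of 29 others. The simulated genes varied independently of each other, whereas camera estimated a correlation of 0.33 among the measured cell division genes. The simulation therefore does not show how often the list test errs among correlated genes.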

Results

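Liver RNA of female Wistar rat pups was measured on 9 single-colour microarrays, 1 array per pup. The 4 control pups were not separated from their mothers, and the 5 separated pups spent 4 h away from them and 24 h back with them before the liver was taken. The labels give an age of 10 days for both groups. They give the same age at the separation, although the livers of separated pups were taken after 24 h back with the mother. Whether separated pups were about a day older than controls is therefore not known, and such a difference could not be told apart from separation. The labels also give at least 3 litters, without saying which pup came from which litter. The p-values therefore measure the spread between these pups, and pups of 1 litter cannot be told from unrelated ones. The comparison asks whether a single short absence of the mother leaves a trace in the liver's gene expression about a day later, in a study that was also concerned with a leaky gut and with gut bacteria reaching other organs. Between 55.4% and 64.0% of the probes were well above background on each array, the lower value on the array of separated pup 1. The 75th percentile of the signal lay between 1521 and 2523 on control arrays and between 1063 and 1993 on the others. Any pair of arrays correlated across probes at 0.972 to 0.991, where probes are not independent replicates. The number of arrays limits the precision.

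The livers of separated pups held more mRNA for Ppara, the nuclear receptor that switches on fat burning, for Cpt1a, the enzyme that admits fatty acids into mitochondria, and for Abcc3, a pump that moves bile acids and conjugated compounds from hepatocytes back to the blood. They held less mRNA for 12 of 29 measured cell division genes, such as Ccnb1 (cyclin B1), and for Fos, an immediate early transcription factor. Of 11962 genes tested, 516 passed the limma test at an adjusted p under 0.05, and 392 of these were higher and 124 lower in separated pups. At an unadjusted p under 0.05 there were 2311 genes, 19.3% of those tested, against 598 by chance alone. The median log2 difference over all genes was 0.03, while it was 1.06 among the higher genes and −0.70 among the lower ones. The excess of higher genes followed the scaling of the arrays. The same signals gave 264 higher and 329 lower genes with quantile normalization, and 226 higher and 695 lower with each array centred on its median, which moved the median of all genes to −0.24. The deposited value table gave 319 higher and 294 lower genes.

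The largest rises by size were spread over genes of different functions. Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, rose by 3.10 ± 0.36 on the log2 scale (difference ± SE, limma adjusted p = 0.00237). Abcc3 rose by 3.04 ± 0.32 (limma adjusted p = 0.00146), from −5.02 ± 0.55 (SD, n = 4) to −1.98 ± 0.54 (SD, n = 5) relative to the array's 75th percentile. The deubiquitinase Otud1 rose by 2.84, the lysosomal peptidase Prcp by 2.84, the death effector domain protein Dedd by 2.78, Parg, which removes poly(ADP-ribose) chains, by 2.73, and the zinc finger gene Zbtb41 by 2.61. The monoamine transporter Slc18a2 rose by 2.54 and the transcriptional repressor Bhlhe40 by 2.52. The probes of Prcp and Slc18a2 were well above background in only 1 control pup each and those of Parg and Zbtb41 in 2 each, so the size of these 4 rises rests on dim control values. The probes of Nf1, a brake on Ras, of Jdp2, a partner of Jun proteins, and of C2cd4b were not well above background in any control pup, and these genes were at least 2.88-fold, 3.18-fold and 2.34-fold higher. For C2cd4b this holds for the group means only, since its probe was well above background in only 4 separated pups. Separated pup 4, at −6.85, lay below control 2, at −6.67, so the groups overlap for this gene. The largest fitted falls were those of Fos and of Lgi1 and Taar1, a secreted protein and an amine receptor known mainly from the brain. Their probes and that of Cysrt1 were not well above background in any separated pup, and the genes were at least 2.96-fold, 1.52-fold, 2.00-fold and 1.26-fold lower in that order. The bounds of Lgi1, Taar1 and Cysrt1 lie below the 2.32-fold fall of Fbxo5, so the rank of these genes by size is not settled. Among the other large falls, Fbxo5, an inhibitor of the anaphase-promoting complex, fell by 1.21, the mitotic kinase Pbk by 1.16, Mastl, the kinase that holds cells in mitosis, by 1.06, the kinetochore gene Ska1 by 1.05 and the ATPase Fignl1 by 1.04.

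The probe of Abcc3 (gene ID 140668) lies on chromosome 10 from 82987122 to 82987181, that of Ppara (25747) on chromosome 7 from 123807031 to 123807090, and that of Cpt1a (25757) on chromosome 1 from 205912066 to 205912125. The probe of Fos (314322) lies on chromosome 6 from 109561941 to 109562000, and that of Ccnb1 (25203) on chromosome 2 from 31574809 to 31575048. These coordinates are of the rn4 build that the array files name. Whether a probe falls in a coding exon or an untranslated region was not determined, because no annotation of that build was used here.

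**Figure D1:**
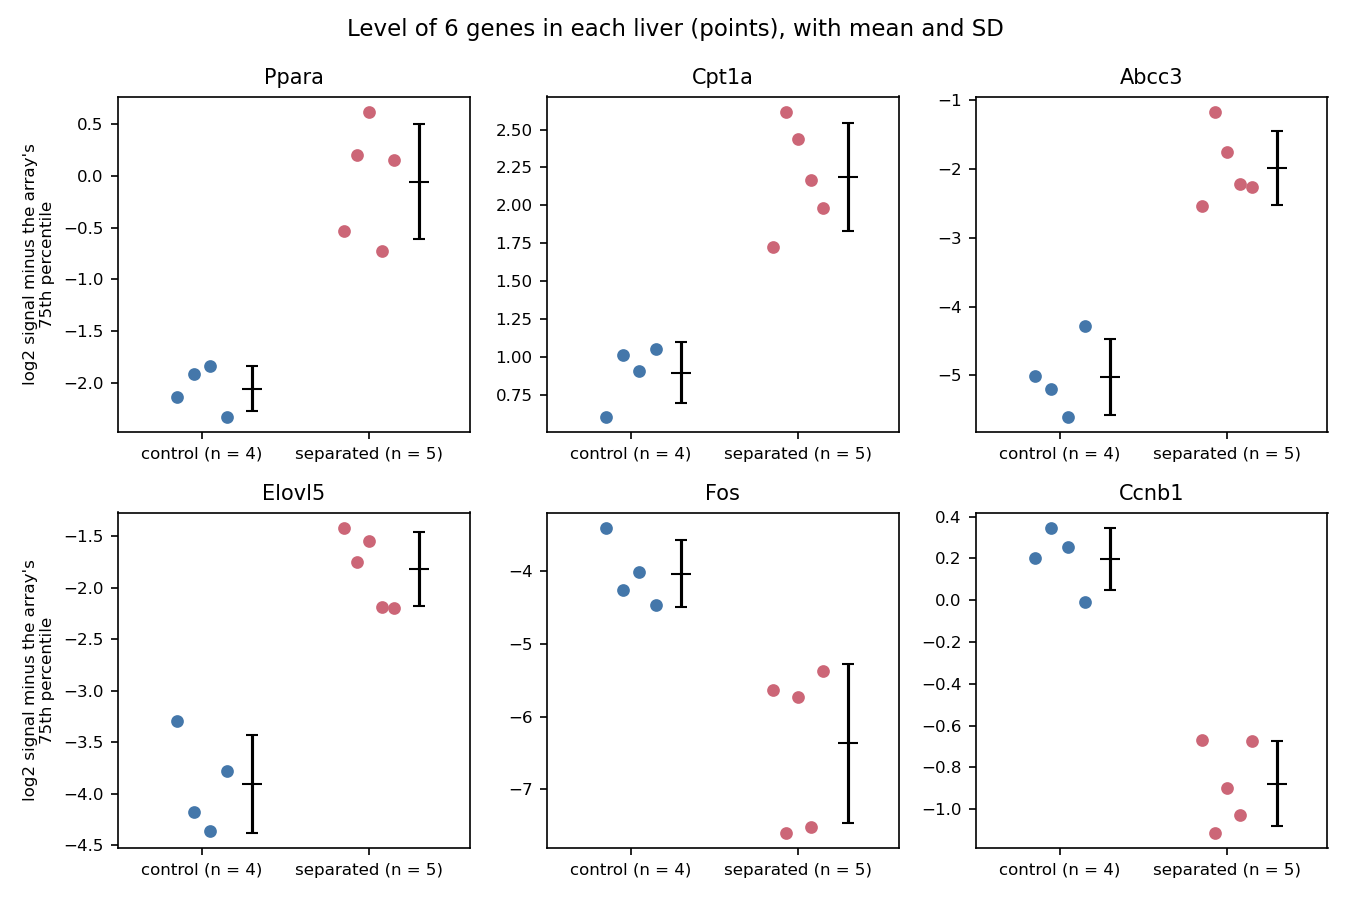
Level of 6 genes in each liver, as log2 signal minus the array's 75th percentile (vertical axis), in 4 control pups (blue points) and 5 separated pups (red points), with the mean and SD of each group as a black bar; the axes do not start at 0. Every separated pup lies above every control for Ppara, Cpt1a, Abcc3 and Elovl5 and below every control for Fos and Ccnb1, and Fos was not well above background in any separated pup.

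Cell division genes were lower as a group. Of 29 measured members of the list, 12 fell, none rose and 17 did not pass, with a median log2 difference of −0.60, and 24 were lower when adjusted over the list alone. Ccnb1 fell by 1.07 ± 0.14 (difference ± SE, limma adjusted p = 0.00322), from 0.20 ± 0.15 (SD, n = 4) to −0.88 ± 0.20 (SD, n = 5), which is a 2.11-fold lower level. Kif20a, a motor protein of late mitosis, and Bub1b, a spindle checkpoint kinase, each fell by 1.04, and Plk1, a kinase needed for spindle formation, fell by 0.94. Cenpf, Nusap1, Bub1, Aurkb, Ccnb2, Top2a, Foxm1 and Tpx2 fell by 0.92 to 0.59. A second probe of Top2a lay at 0.44 and did not pass, so that the probes of this gene disagree in direction. Second probes of Cenpf and Foxm1 lay at −0.47 and −0.18, nearer to 0 than the −0.92 and −0.66 of the probes that stand for these genes. Members that work in DNA replication did not pass over all probes, such as the helicase subunit Mcm4 at 0.35, a second probe of which lay at 3.05 and which passed as the mean of its probes, and the sliding clamp Pcna at −0.36. Only 3 of the 29 members lay above 0, Mcm4 among them. The 24 that were lower over the list alone outnumber the 18 genes of mitosis, so they include genes of replication. The list passed camera at an adjusted p of 1.07e-15, against an adjusted p = 0.299 with an estimated correlation. Its mean level was −0.35 ± 0.16 (SD, n = 4) in controls and −0.88 ± 0.14 (SD, n = 5) in separated pups, a difference of −0.53 (exact two-sided permutation p = 0.0159, adjusted over the 30 lists 0.0794). On the slides that held both groups the difference was −0.55 and −0.47. With slide as a block, Kif20a, Ccnb2, Aurkb, Bub1, Nusap1, Tpx2 and Foxm1 no longer passed, while the list did, and its median was −0.58. With the array's 5′ minus 3′ value as a covariate the median of the list was −0.42, the list passed and 6 of the 12 genes did.

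**Figure D2:**
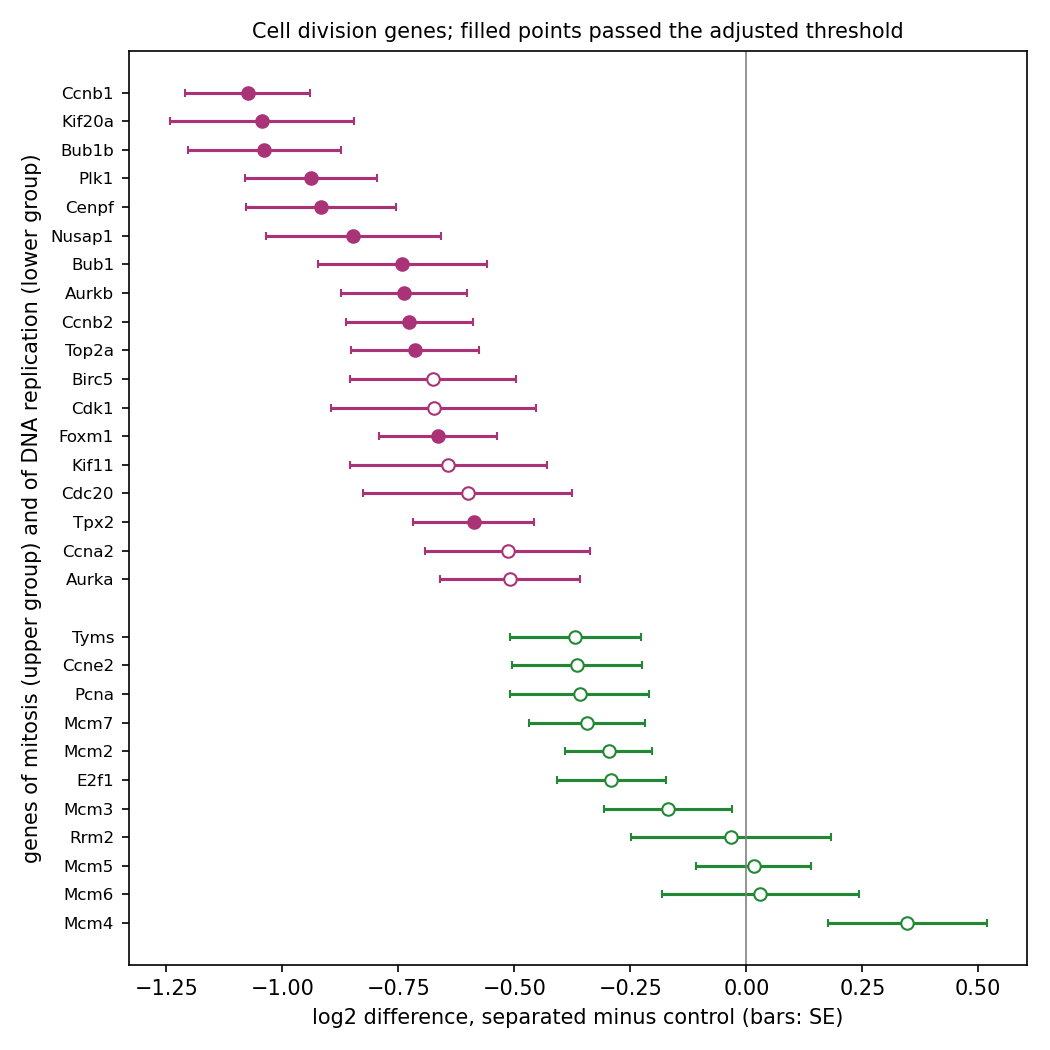
Log2 difference between separated and control pups (horizontal axis, bars give the SE) for the 29 measured cell division genes, with the 18 genes of mitosis above and the 11 of DNA replication below; filled points passed the adjusted threshold. All genes of mitosis lie left of 0, down to −1.07 for Ccnb1, while the genes of replication lie between −0.37 and 0.35 and 0 of them passed limma over all probes. This split of the list was drawn after the results had been seen.

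Immediate early genes, which respond to growth signals and stress within minutes, were lower as well. Of 16 measured members, Fos and Klf6 fell and 14 did not pass, with a median log2 difference of −0.38, and 3 were lower when adjusted over the list alone. Klf6, a zinc finger transcription factor, fell by 0.96 ± 0.20 (difference ± SE, limma adjusted p = 0.0255). Ccn1, a matrix signalling protein, lay at −0.87 (limma adjusted p = 0.0696) and the nuclear receptor gene Nr4a1 at −0.50 (limma adjusted p = 0.127), and they passed in 5 and 4 of the 28 other settings, with that without control 1 among those of Nr4a1. The list passed camera at an adjusted p of 2.85e-04, against an adjusted p = 0.135 with an estimated correlation. Its mean level differed by −0.46 (exact two-sided permutation p = 0.0159, adjusted 0.0794), and by −0.45 and −0.49 on the slides that held both groups. Fos no longer passed with slide as a block.

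Single genes of fat and bile acid handling rose, and fatty acid oxidation rose as a list in some settings. In fatty acid oxidation and ketogenesis, 2 of 26 measured members rose, also when adjusted over the list alone. These were Ppara, by 2.00 ± 0.27 (difference ± SE, limma adjusted p = 0.00376), from −2.05 ± 0.22 (SD, n = 4) to −0.06 ± 0.56 (SD, n = 5), and Cpt1a, by 1.29 ± 0.19 (limma adjusted p = 0.00624), from 0.89 ± 0.20 (SD, n = 4) to 2.19 ± 0.36 (SD, n = 5). The other 24 members did not pass, 20 of the 26 lay above 0, and the list's camera adjusted p was 0.140, or 0.751 with an estimated correlation. In the 28 other settings that value ran from 0.0158 to 0.462, always in the direction of a rise, and the list passed in 5 of them, with quantile normalization, median centring, the deposited value table, within slide 1 and without control 4. In bile acid synthesis and transport, 2 of 21 rose, and 3 when adjusted over the list alone. They were Abcc3 and Hsd3b7, an enzyme of bile acid synthesis, by 1.51, whereas Cyp7a1, the rate-limiting enzyme of that synthesis, lay at −0.39 (limma adjusted p = 0.481), at −0.67 without control 4 and at −0.24 without control 1. The list's camera adjusted p was 0.450. Of 15 lipogenesis genes, the fatty acid elongase Elovl5 rose by 2.08. Camera gave the lipogenesis list an adjusted p of 0.403 and the list of 26 cholesterol synthesis genes 0.221, and the latter passed as lower within slide 2 and without control 1. Its mean level differed by 0.17 on slide 1 and by −0.19 on slide 2.

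Several genes that fold proteins or respond to stress rose. In the unfolded protein and amino acid stress response, 3 of 23 measured members rose, and 4 when adjusted over the list alone. Pdia4, which forms disulfide bonds in the endoplasmic reticulum, rose by 1.74 ± 0.25 (difference ± SE, limma adjusted p = 0.00550), Calr, a calcium-binding chaperone of the same compartment, by 1.20 and Sesn2, a stress-induced regulator of growth signalling, by 1.15. The other 20 members did not pass. Among 16 heat shock genes, Hsph1 rose by 1.16. Among 15 genes tied to oxidative stress, Gsr, which regenerates glutathione, rose by 1.65, Hmox1, which degrades heme, by 0.94 and the peroxidase Prdx1 by 0.65, and Nfe2l2, the transcription factor that drives this list, fell by 0.65. The counts adjusted over the list alone were 4 higher and 1 lower in the oxidative stress list and 1 higher among heat shock genes. None of these lists passed camera in the main setting, with adjusted p of 0.140, 0.324 and 0.435. The unfolded protein list passed with quantile normalization and in the deposited value table, in a range of 0.0243 to 0.526 over the 28 other settings, all in the direction of a rise, and it passed fry (adjusted p = 0.00586), against 0.392 by camera with an estimated correlation. The mean level of the unfolded protein list was 0.89 ± 0.07 (SD, n = 4) in controls and 1.17 ± 0.06 (SD, n = 5) in separated pups, a difference of 0.28 (exact two-sided permutation p = 0.0159, adjusted 0.0794).

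**Figure D3:**
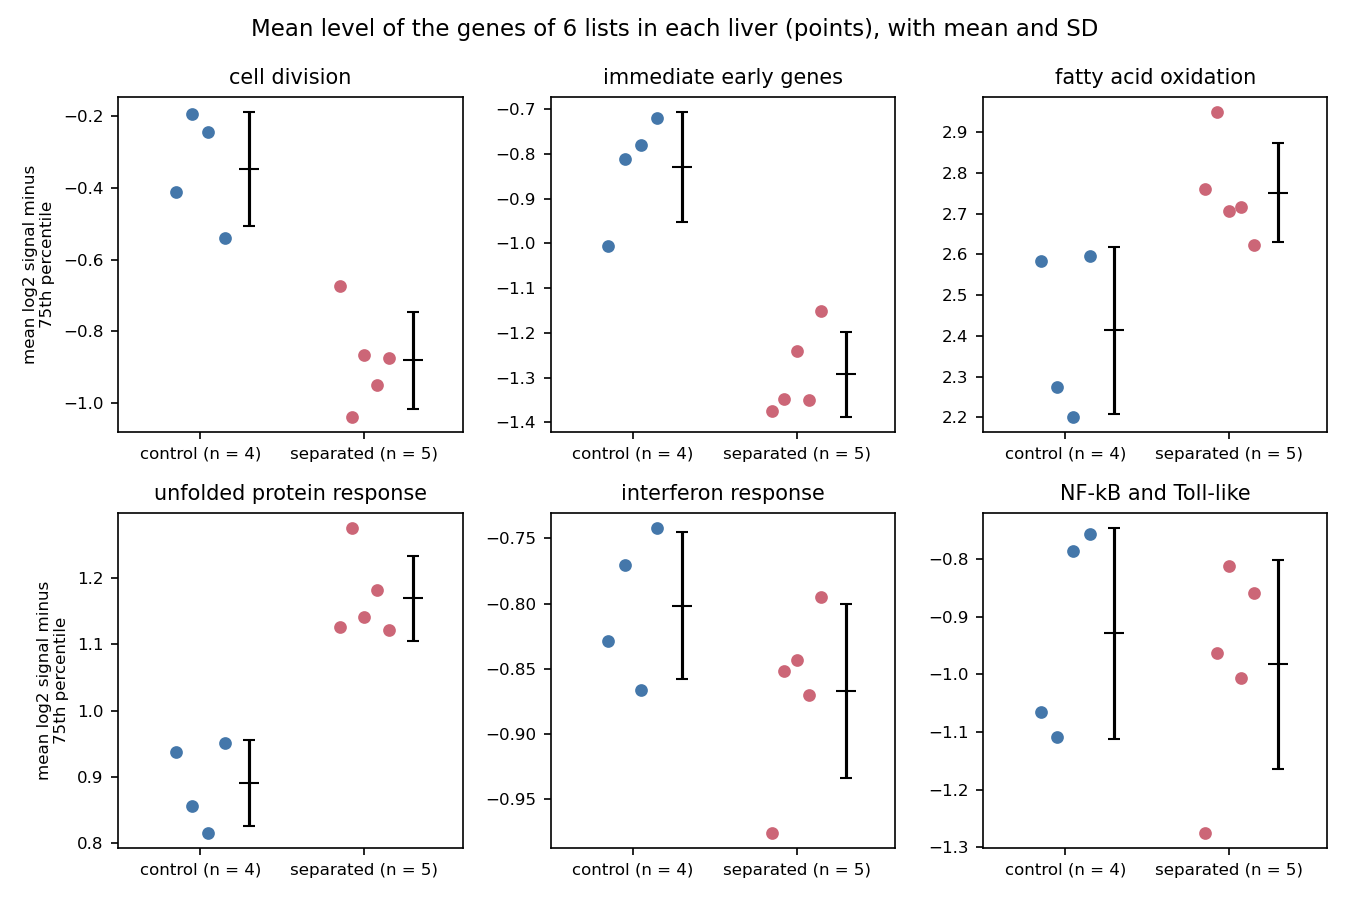
Mean level of the measured genes of 6 lists in each liver, as log2 signal minus the array's 75th percentile (vertical axis), in 4 control pups (blue points) and 5 separated pups (red points), with the mean and SD of each group as a black bar; the axes do not start at 0. The groups do not overlap for cell division, immediate early genes, fatty acid oxidation and the unfolded protein response (exact two-sided permutation p = 0.0159 each, adjusted 0.0794), and they overlap for the interferon list (exact p = 0.143) and the NF-kB list (exact p = 0.714).

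Stress hormone and clock genes gave single calls, and their lists passed in some settings only. Of 21 measured glucocorticoid-responsive genes, only the kinase Sgk1 passed, higher by 1.37 (limma adjusted p = 0.0494), and 4 were higher when adjusted over the list alone. Fkbp5, a co-chaperone of the glucocorticoid receptor, lay at 0.46 (limma adjusted p = 0.0711) and passed in 3 of the 28 other settings, Pck1, a gatekeeper of glucose production, at 0.64 (limma adjusted p = 0.238) and Tsc22d3, an early target of the receptor, at 0.20 (limma adjusted p = 0.534), or at −0.07 with each array centred on its median. Of 13 gluconeogenesis genes, the alanine aminotransferase Gpt2 rose by 0.69, and a second probe of it lay at 0.22. In the circadian clock list, Bhlhe40 rose and Clock, which encodes a core activator, rose by 0.51, while 13 of 15 members did not pass. When adjusted over the list alone, 5 were higher and 1 lower. Camera gave adjusted p of 0.163 for the glucocorticoid list, 0.403 for gluconeogenesis and 0.140 for the clock. Over the 28 other settings these values ran from 0.00309 to 0.792, from 0.000617 to 0.939 and from 0.0320 to 0.394. The glucocorticoid list passed with quantile normalization, median centring and within slide 1, gluconeogenesis within slide 1, and the clock with median centring and by fry (adjusted p = 0.0283), each as higher. With an estimated correlation the adjusted p were 0.747, 0.770 and 0.475. Within slide 2 camera placed the glucocorticoid and gluconeogenesis lists lower without passing, and the mean level of gluconeogenesis genes differed by 0.61 on slide 1 and −0.19 on slide 2.

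Genes that sense or fight bacteria gave no call in the main setting. Of 18 measured genes of the NF-kB and Toll-like receptor response, 29 of the interferon response and 19 of bacterial recognition and killing, 0 passed limma, also when adjusted over each list alone, and camera gave adjusted p of 0.203, 0.221 and 0.329. The medians were −0.19, −0.12 and −0.15, and camera placed these lists lower in all 28 other settings without passing. Among the interferon genes near to passing were Psmb9, an immunoproteasome subunit, at −0.45 and the antiviral gene Mx2 at 0.58, with limma adjusted p of 0.0599 and 0.0808. In the other lists, Nod1, an intracellular sensor of bacterial wall fragments, lay at −0.38 and its relative Nod2 at 0.32, and the inflammatory cytokine Il1a at −0.45 and the mitochondrial superoxide dismutase Sod2 at 0.38, with limma adjusted p of 0.0917, 0.292, 0.167 and 0.232. Of the 28 other settings, Psmb9 passed in 9, among them quantile normalization, the deposited value table and that without separated pup 1, Mx2 in 4, among them that without separated pup 5, Nod1 in 4, and Il1a in 2, with median centring and without control 1. Nfkbiz, a regulator of NF-kB, and Tlr5, the receptor of bacterial flagellin, passed as lower without control 1 alone, at −0.68 and −1.04, Irf7, an interferon regulator, with median centring alone, and Ncf4, a subunit of the phagocyte oxidase, in 2 settings. Lbp, which binds bacterial lipopolysaccharide, lay at 0.30 ± 0.27 (difference ± SE), its co-receptor Cd14 at −0.20 ± 0.22 and the lipopolysaccharide receptor Tlr4 at −0.18 ± 0.20. Hamp, the iron hormone hepcidin, lay at 1.94 ± 1.13, and Lcn2, which traps bacterial iron carriers, at −1.26 ± 1.07, both with a wide spread between pups. Hamp differed by 2.65 on slide 1 and by 0.61 on slide 2, and by at most 3.07 when 1 pup was left out (control 4). Leaving out 1 pup moved Lcn2 to between −1.94 (separated pup 2) and −0.57 (separated pup 3), Lbp to between 0.11 (control 1) and 0.50 (control 4), Cd14 to between −0.37 (control 1) and −0.05 (separated pup 1) and Tlr4 to between −0.33 (separated pup 5) and −0.09 (separated pup 2). The limma adjusted p of these 5 genes lay at 0.356 or above. Of 23 acute phase genes, the interleukin-1 receptor Il1r1 rose by 1.55 and the cytokine-signalling brake Socs3 by 0.67, while the acute phase protein A2m lay at −0.31 (limma adjusted p = 0.228) and passed with median centring alone. The probe of Il1r1 was well above background in only 2 controls, so the size of its rise rests on dim control values. The acute phase list had a camera adjusted p of 0.221 and passed as higher within slide 1. None of the antigen presentation (13), complement (19) and negative acute phase (12) genes passed, though the last list passed camera as higher within slide 1 and without separated pup 4.

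Markers of other cells of the liver did not separate the groups as lists in the main setting. Of the 16 cell type lists with at least 5 measured members, 0 passed camera, the smallest adjusted p being 0.239 for cholangiocytes, and 2 had an unadjusted p under 0.05, while fry called 0. The cholangiocyte list had a median of −0.51 and a mean level lower by 0.32 (exact two-sided permutation p = 0.0952). Camera placed it lower in the 27 other settings that tested it, and it passed within slide 2. The list of sinusoidal and vascular endothelium had the smallest exact p of these lists, 0.0317 (adjusted 0.508), at a difference of 0.21, or 0.13 without control 3. The eosinophil, mast cell and basophil list had a median log2 difference of 1.78 with a wide spread between pups (exact two-sided permutation p = 0.159). Its mean level differed by 1.37, and by 0.78 without control 3. The erythroid list differed by 0.28 (exact p = 0.476), by 0.67 without control 4, where it passed camera, by 0.06 without control 1 and by 0.12 without separated pup 2, the neutrophil list by 0.38 (exact p = 0.429), the Kupffer cell list by −0.08 (exact p = 0.714) and the hepatocyte list by 0.22 (exact p = 0.222). Leaving out 1 pup gave 0.08 (separated pup 2) to 0.62 (control 4) for neutrophils, −0.16 (control 1) to 0.04 (separated pup 1) for Kupffer cells and 0.11 (control 1) to 0.31 (control 4) for hepatocytes. The neutrophil list passed camera as higher within slide 1 and as lower within slide 2. Exocrine pancreas, adipocyte and sex-linked markers had too few measured members to be tested as lists. The 4 measured adipocyte markers all lay higher, Fabp4 by 0.81, Retn by 0.58, Cidec by 0.43 and Cfd by 0.39, of which Fabp4 and Cidec passed when adjusted over the list alone and none did over all probes in the main setting, while Fabp4 did in the deposited value table and Cidec with array weights. Retn and Cfd lay at −0.10 and −0.04 within slide 2, Fabp4 at 0.52 without control 3, Retn at 0.22 without separated pup 2 and Cfd at 0.21 without control 1. The mean level of the 4 was −0.25 ± 0.09 (SD, n = 4) in controls and 0.30 ± 0.28 (SD, n = 5) in separated pups, and every separated pup lay above every control.

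Calls were uneven over the probes of the array. With the probes ranked by signal into 10 sets of like size, the dimmest set held 98 higher and 8 lower calls, and the brightest 18 and 4. Higher calls were most frequent in the third set, with 133, and lower calls in the fourth, with 32. Of 187 probes with over 65% G and C, 47 were called higher and 0 lower, with a median log2 difference of 0.77, and that of C2cd4b belongs to these with 86.7%. Over 1915 genes with probes at different distances from the 3′ end, the median 5′ minus 3′ log2 value was −1.68 ± 0.08 (SD, n = 4) in controls and −1.56 ± 0.15 (SD, n = 5) in separated pups (exact two-sided permutation p = 0.190). Separated pup 1 lay at −1.79, below every control. The other separated pups lay at −1.58 to −1.41, above the highest control at −1.60. On the slides that held both groups the difference was 0.03 and 0.28. The median difference was −0.05 for probes up to 500 bp apart, 0.16 up to 2000 bp, 0.19 up to 10000 bp and 0.23 beyond. The exact p therefore does not exclude a difference in RNA length between the groups. Of 80 changed genes with another tested probe, 64 had every other probe in the same direction and 19 had another one called the same way. These counts were 48 and 17 for the 57 higher genes among them, and 16 and 2 for the 23 lower genes. Of 170 pairs of a 5′ and a 3′ probe with a higher call, 124 had both probes above 0 and 15 had both called. In 116 only the dimmer probe was called. Of 33 such pairs with a lower call, 26 had both probes below 0 and 1 had both called.

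All 57 changed genes named in the text or in its lists kept their direction on both slides that held both groups, which is partly built in because they were chosen for passing on these arrays. Of the 11908 genes measured on every array, chosen by no test, 1216 or 10.2% had groups that did not overlap, 699 with separated pups higher and 517 lower, against 1.59% by chance. With slide as a block 394 genes passed, 339 higher and 55 lower, and 39 of the 57 kept their call. The other 18 lost it, and not all of them are marked as such above. With that block the 392 higher and 124 lower genes all kept their direction, with medians of 1.12 and −0.72. Within slide 1 alone 4 genes passed and within slide 2 alone 0, at 1048 and 1456 genes with an unadjusted p under 0.05. Separated pups lay at positions 1 and 2 of each slide and controls at positions 3 and 4, so that position and group cannot be told apart.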

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

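The tests of scaling, of the length of the RNA (for both patterns), of G and C content, of slides and of red cell precursors were chosen after the results had been seen, while the counts over other splits of the pups had been fixed beforehand.

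Over 276 sets of values of 1 list or 1 gene in 1 group, 19 held a pup far from the others, against 13.8 by chance. Controls 1 and 4 account for 11 of the 19 and separated pup 1 for 3. Values are log2 levels relative to the array's 75th percentile. In control 1, the mean level was 0.71 for cholesterol synthesis genes, where the other controls lay between 1.30 and 1.40, and 2.32 for urea cycle and amino acid genes, where they lay between 2.63 and 2.69. The same pup held Prcp at −5.77 against −8.12 to −8.02, Klf6 at −0.69 against 0.02 to 0.08, Nfkbiz at −3.02 against −2.06 to −1.96 and Nr4a1 at −2.99 against −2.40 to −2.28. In control 4, the mean level of oxidative stress genes was 0.78 against 0.47 to 0.51, Hmox1 lay at 1.23 against 0.48 to 0.57, Pbk at −2.09 against −1.38 to −1.24, Irf7 at −0.39 against −0.90 to −0.82 and Pck1 at 3.84 against 2.93 to 3.04. Control 3 held Fabp4 at −2.11 against −0.996 to −0.938. Among separated pups, pup 1 held Psmb9 at 0.81 against 0.42 to 0.52, Ncf4 at 0.0114 against 0.34 to 0.39 and Cyp7a1 at −2.18 against −3.16 to −2.93. Pup 2 held Top2a at −1.01 against −0.65 to −0.52, pup 3 Clock at −3.24 against −3.68 to −3.61, and pup 5 Calr at 2.45 against 3.23 to 3.52. In pup 4, the mean level of bile acid genes was 0.82 against 0.99 to 1.06.

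Of the changed genes, 392 were higher and 124 lower after separation. Without probes over 60% G and C, 389 of the 392 higher genes were still tested and 75.5% of the changed genes were higher. So few of these genes rest on such probes that their removal could hardly move the share. It shows only that probes over 60% G and C do not make up the excess, and composition below that was not tested. With the array's 5′ minus 3′ value as a covariate 76.7% were higher, which argues against a shorter RNA in controls as the whole cause. With that covariate the median of the 392 genes moved from 1.06 to 1.00 and 171 of them passed, while the 5′ probe rose more in 57.6% of 170 probe pairs with a higher call (exact binomial p = 0.0549), so a part from RNA length stays open. With quantile normalization only 44.5% of the changed genes were higher, which indicates that the excess may come from how dim probes are scaled. That setting still called 262 of the 392 higher and gave all 392 a positive difference, for which separation itself and the position on the slide, which goes with it, stay open.

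The fall of cell division genes was weighed too. On the slide where their mean level differed least it differed by −0.47, which argues against a difference between slides as the cause. Their level went down as the array's 5′ minus 3′ value went up, with a slope of −0.867 ± 0.322 (SE) in a model that also held the group. With that value as a covariate the difference moved from −0.534 ± 0.098 (SE) to −0.428 ± 0.081, which argues against RNA length as the whole cause. A part from it stays open, since 6 of the 12 changed members no longer passed, although all 12 stayed lower. Of these 6, Kif20a, Top2a, Bub1 and Nusap1 moved from −1.04, −0.71, −0.74 and −0.85 (SE 0.199, 0.138, 0.182 and 0.189) to −0.81, −0.63, −0.51 and −0.61 (SE 0.172, 0.148, 0.139 and 0.154), and their calls ended with a smaller difference. Ccnb2 and Tpx2 moved from −0.73 and −0.59 (SE 0.136 and 0.131) to −0.74 and −0.66 (SE 0.157 and 0.143), and theirs ended without a smaller difference, with a larger SE and a covariate that takes up a degree of freedom. The erythroid list, tested because red cell precursors divide in the liver of young pups, differed by 0.28 in the other direction, 1.88 standard errors from the fall of −0.53 in cell division genes, so a smaller number of such cells cannot be told apart from fewer dividing cells of another kind at this spread. Control 4 sets much of that spread, at −0.10 against −1.92 to −1.50 in the other controls. Without it the erythroid list differed by 0.67, 5.91 standard errors from the fall, and without separated pup 1 by 0.34, 2.07 standard errors from it, while leaving out any other pup gave 1.17 to 1.96. Each of these standard errors is that of the erythroid difference alone. The fall of cell division genes was taken as fixed, although both come from the same pups. On the slides that held both groups the erythroid list differed by 0.94 and −0.37, so the question stays open. The most abundant genes of that list, the globins Hbb-b1 and Hbb, lay at 7.84 ± 0.30 and 6.63 ± 0.40 (SD, n = 4) in controls and at 8.06 ± 0.34 and 6.97 ± 0.34 (SD, n = 5) in separated pups, and Hbb-b1 differed by −0.22 with quantile normalization. A second probe of Hbb lay at 2.07 and one of Hbb-b1 at 0.11, and Hbb passed as the mean of its probes, at 1.21. Fewer dividing hepatocytes after separation may be a candidate explanation too, and no value here tests which cells divide.

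With the pups taken as independent, a number of changed genes as large as this was unlikely by chance. Which pups shared a litter is unknown, so a chance gathering of littermates in 1 group is not covered. Of 100 splits of the 9 pups into 4 and 5, drawn from the 126 possible with the real one included, only the real one reached 516 genes. The highest other count, 339, came from the split that turns the real groups round with 1 separated pup placed among controls. The real split alone reached 392 higher genes, against 65 as the highest other count, and 2311 genes at an unadjusted p under 0.05, against 2202. For the 124 lower genes, 2 splits reached as many, the other being the same turned split with 274. In the direction of the real groups that split holds 274 higher and 65 lower genes, so that neither 392 nor 124 was reached by it in that direction. Chance cannot be excluded for the number of lists past camera's threshold, because 89 of the 100 splits gave at least the 2 lists found and the highest other count was 13. For cell type lists all 100 splits gave at least the 0 found, and the highest other count was 8.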

How the results depend on the processing

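The probe nearest the 3′ end, the removal of probes rich in G and C and the 5′ minus 3′ covariate were chosen after seeing the data. None of the 57 named genes past the threshold changed direction in a setting that tested it, which all 28 did except the deposited value table (53 tested), the filter that needs all 9 arrays (42) and the removal of probes rich in G and C (56). Cell division and immediate early genes passed camera at its preset correlation in all 28, with medians of −0.87 to −0.42 and −0.65 to −0.24. With an estimated correlation neither list passed in the main setting (camera adjusted p = 0.299 and 0.135). The number of changed genes (516) was 921 with median centring, 343 without a filter, 1354 with array weights, 240 with the covariate, 4 within slide 1 and 0 within slide 2, where fewer pups entered. Leaving out 1 pup gave 160 to 831: 180 without control 2, 160 without control 3, 330 without control 4, 831 without separated pup 1, 251 without separated pup 2 and 309 without separated pup 3. The higher genes (392) numbered 226 with median centring, 942 with array weights, 184 with the covariate, 4 and 0 within slides 1 and 2, and 136 to 651 without 1 pup. The lower genes (124) numbered 329 with quantile normalization, 695 with median centring, 223 with normexp, 234 without background correction, 294 in the deposited value table, 59 without a filter, 412 with array weights and 56 with the covariate. They numbered 55 with slide as a block, 40 on the slides that held both groups with slide as a block, 0 within slide 1, 0 within slide 2 and 24 to 180 without 1 pup. Genes at an unadjusted p under 0.05 (2311) numbered 3705 with median centring, 1048 within slide 1 and 1456 within slide 2. The cause of these shifts was not tested.

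The gene lists past the threshold (2) numbered 5 with quantile normalization, 5 with median centring, 4 in the deposited value table, 8 within slide 1, 4 within slide 2, 5 with fry and 0 with an estimated correlation. Cell type lists (0) numbered 1 with median centring, 1 with normexp and 1 without background correction, each time the eosinophil list, 1 without control 4, the erythroid list, 2 within slide 1 and 4 within slide 2. Uncalled genes that changed sign were Lbp within slide 2 (−0.23), Tlr4 within slide 2 (0.14), Lcn2 within slide 1 (0.59), Retn within slide 2 (−0.10), Cfd within slide 2 (−0.0387), Tsc22d3 with median centring (−0.0725) and Hbb-b1 with quantile normalization (−0.22), median centring (−0.0483) and the deposited value table (−0.15). The cause was not tested. Of the 57 named genes, 50 passed with quantile normalization, 39 with slide as a block, 27 without control 2 and 28 without control 3. Camera's direction was lower against a positive median for oxidative phosphorylation (0.03) and megakaryocytes (0.09), and the urea cycle list had a median of −0.06 and a mean of 0.07. Dim probes, those not well above background on 4 arrays, were not tested in the main setting.

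The labels give both groups replicate numbers without saying that a number marks a litter. Deviations of pups with the same number correlated at 0.06, −0.04, 0.18 and 0.14, and pups numbered 3 and separated pup 4 correlated best with their own number. So few pairs cannot settle whether a number pairs the pups. With the replicate block over replicates 1 to 4, 159 genes passed, 146 higher and 13 lower.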

Other observations

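The comparison of mitosis with DNA replication and that of the clock's arms were chosen after the results had been seen.

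Some genes of growth and amino acid handling rose singly. In the growth hormone and insulin-like growth factor list, Socs2, a brake on growth hormone signalling, rose by 1.07 ± 0.15 (difference ± SE, limma adjusted p = 0.00471) and the binding protein Igfbp4 by 0.79, while the other 12 of 14 members did not pass (camera adjusted p = 0.229). In the urea cycle and amino acid list, Cth, which makes cysteine, rose by 0.77 and Slc25a15, the mitochondrial ornithine carrier, was at least 1.61-fold higher, its probe not being well above background in any control, while 22 of 24 did not pass (camera adjusted p = 0.725). The probe of Slc25a15 was well above background in only 4 separated pups. Of 15 cell junction genes, Cgn, a protein of tight junctions, rose by 1.13, and the list's mean level differed by 0.22 (exact two-sided permutation p = 0.0159, adjusted 0.0794). The list had an adjusted p of 0.229 by camera, 0.597 by camera with an estimated correlation and 0.0283 by fry. Of 28 genes of drug and steroid metabolism, the aryl hydrocarbon receptor Ahr rose by 1.29 (limma adjusted p = 0.00332). Ribosomal proteins (34) and oxidative phosphorylation (33) held 0 genes past limma's threshold, with median differences of 0.05 and 0.03. The hypoxia response (16), glycolysis (14) and fetal liver genes (8) held 0 as well. The 1 changed member was Hmox1 among 17 iron and heme genes and Sesn2 among 15 targets of p53.

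Granule proteins of eosinophils had some of the largest uncalled differences. Prg2 lay at 2.06 ± 1.01 (difference ± SE), Prg3 at 2.29 ± 1.12 and the peroxidase Epx at 2.08 ± 0.89, with limma adjusted p of 0.274, 0.272 and 0.213. Prg2 spread by 2.26 (SD, n = 4) among controls and by 1.33 (SD, n = 5) among separated pups. Control 3 lay lowest, and without it the differences were 0.97, 1.13 and 1.31. The list of which they are part did not pass at an adjusted p of 0.330.

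A hypothesis is that the fall in cell division genes is a fall of mitosis more than of DNA replication. The 18 measured genes of mitosis had a mean difference of −0.76 and the 11 of replication −0.17, with exact two-sided permutation p of 0.0159 and 0.0794. The difference between both arms was −0.59, and −0.62 and −0.51 on the slides that held both groups. Its exact two-sided permutation p of 0.0159, the smallest that 9 pups allow, decides nothing, because the arms were drawn on these arrays once mitosis genes had been seen to pass and replication genes not to. The cell cycle stage of the cells was not measured.

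Because clock genes such as Bhlhe40 and Clock were higher, a difference in the hour at which livers were taken might have been involved. That would move the morning and evening arms of the clock apart. The morning arm differed by 0.35 and the evening arm by 0.11, and the difference between them was 0.24 (exact two-sided permutation p = 0.524), which gives no sign of such a shift but cannot exclude one of this size.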
